A study of Mus musculus with 4 samples.

How the data were processed

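The series holds 4 ATAC-seq libraries of adipose progenitors from mouse fat, 2 from subcutaneous (SAT) and 2 from visceral (VAT) tissue. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, fresh cells were lysed in a detergent buffer and treated with Nextera transposase, and libraries were amplified by PCR with Nextera index primers. Per the submitters' processing notes, the reads were processed with Bowtie2 and MACS2 on build mm9, and no versions are given there. The options, the treatment of duplicate reads, any shift of read ends for the transposase and any filter of repeats are not given in the sources used here.

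Each library has 1 deposited peak list with start and end positions and a score per peak, so peaks were called per library and not on pooled replicates. The score in column 5 of the deposited lists is the authors' peak caller score, a whole number of 20 or more. No header says how it is scaled, so it was used only to rank and filter peaks within a list, as a percentile. Scores were not compared between libraries by any test. The lists hold no read counts, so depth is unknown and no detection limit could be set per library. A peak caller finds more peaks in a deeper or cleaner library, so the number of peaks is both a measure of chromatin and of data quality. This affects every comparison with SAT 2, whose list is the shortest.

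Peaks of the 4 lists that overlapped by at least 1 bp were merged, and a merged region counted as open in a library if a peak of that library lay in it. Regions with a peak in both libraries of a depot and in neither of the other were called restricted to that depot. The same rule was applied to the other 2 ways of dividing 4 libraries into 2 pairs: by replicate number, and crossed. No p-value was computed over regions for these counts, since regions are not replicates. Values per library were compared with a two-sided exact permutation test, for which the smallest possible p is 0.333. Overlap of 2 lists was measured as the Jaccard index of covered bases and as the percentage of peaks overlapped. Windows of 1 Mb were assigned by the centre of each region. The dispersion index over windows with at least 10 regions was compared with 1000 shuffles of the class among regions. Shares have 95% Clopper-Pearson intervals, which cover counting error only. Positions are given from 1 on mm9.

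An added measure compared divisions by the log2 ratio of the products of their 2 counts, with 0.5 added to each count and a standard error from leaving out each of 21 chromosomes. It was tested on 83319 simulated regions, with the real share of regions that hold a peak in each library. With no simulated effect the depot log2 ratio was -0.05 ± 0.11. With a simulated depot effect it was 5.48 ± 0.11, and with both a depot and a replicate-number effect it was 6.17 ± 0.15. With a replicate-number effect only it was 0.17 ± 0.20, and the log2 ratio for replicate number was 5.60 ± 0.11. Smaller effects were not simulated, so the simulations do not show whether a weak depot effect would be seen. Interval code was checked against bedtools 2.31.1 and gave the same merged regions and overlaps. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

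The rule for named regions, fixed before the data were examined, took for each depot the 10 restricted regions with the highest score percentile in the weaker of the 2 libraries, and the 5 windows of 1 Mb with the largest net count; of the subcutaneous windows, 2 of the 5 had a net count of 1, tied with others, and appear only among the effects of the processing. Alternatives fixed at the same time were a 50% reciprocal overlap of peaks, merging within 500 bp, the top 50% of each list by score, lists cut to the 22845 highest-scoring peaks, 200 bp around each peak centre, autosomes and X only, a looser rule for replicates, leaving out each library, and a block for replicate number. Promoter status, gene lists (developmental patterning, adipogenic, progenitor, inflammatory, matrix and markers of other cell types) and motif shares had also been planned. These need an annotation or sequence of build mm9. The gene table at hand follows assembly GRCm38, coordinates were not converted between builds, and these parts were not analysed here.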

Results

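Open chromatin was mapped in adipose progenitors, the mesenchymal precursor cells of fat tissue that can form adipocytes. The cells were freshly isolated from the subcutaneous and the visceral fat of C57BL/6 mice aged 16 weeks. The assay was ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, so that clusters of reads mark open chromatin. There were 4 libraries, 2 per depot, called SAT 1 and SAT 2 (subcutaneous) and VAT 1 and VAT 2 (visceral) here. Each library had its own list of peaks on the mouse genome build mm9. The labels do not say whether the 2 libraries of a depot came from separate animals, so the spread between them may be technical. The lists carry no read counts, so the sequencing depth behind each peak is unknown, and a missing peak does not show that a site was closed. No mm9 gene annotation was used here, and regions are therefore given by position, without genes.

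The visceral lists were long and alike, whereas the subcutaneous lists differed from each other more than the depots did. SAT 1 held 56823 peaks and SAT 2 held 22845. VAT 1 held 56907 peaks and VAT 2 held 62279. The mean was 39834 ± 24026 peaks for subcutaneous and 59593 ± 3799 for visceral progenitors (SD, n = 2 each). Peaks covered 15.7 Mb in SAT 1, 5.81 Mb in SAT 2, 16.1 Mb in VAT 1 and 18.2 Mb in VAT 2. Median peak widths lay close together, at 215 bp in SAT 1, 208 bp in SAT 2, 223 bp in VAT 1 and 220 bp in VAT 2. In a two-sided exact permutation test, the difference between depots gave p = 0.333 for peak number, covered length and median width alike, which is the smallest p that 2 libraries against 2 allow. The lowest score was 20 in every list, so all lists ended at the same score of the peak caller.

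The overlap of the lists asked whether progenitors of one depot resemble each other more than they resemble progenitors of the other depot. By the labels as given, the lists of a depot were not closer to each other. The closest pair was SAT 1 and VAT 1, which shared 0.605 of their joint covered bases (Jaccard index). VAT 1 and VAT 2, which come from the same depot, shared 0.506, and SAT 1 and VAT 2 shared 0.512. The 3 pairs with the short SAT 2 list were lower, at 0.328 with SAT 1, 0.322 with VAT 1 and 0.301 with VAT 2. The mean Jaccard index was 0.417 ± 0.126 within depots (SD over 2 pairs) and 0.435 ± 0.148 between depots (SD over 4 pairs), a difference well inside the spread of the pairs. Without SAT 1 the within-depot mean exceeded the between-depot mean by 0.195, because the 2 remaining pairs between depots both hold the short list. Nearly all SAT 2 peaks were present in the visceral lists, 93.6% in VAT 1 and 96.8% in VAT 2, and 93.6% were present in SAT 1. When each list was restricted to its 22845 highest-scoring peaks, SAT 2 peaks were overlapped more often by VAT 2 (79.2%) than by SAT 1 (73.9%) or VAT 1 (72.9%), but by Jaccard index SAT 2 was about equally close to all of them (0.439, 0.437 and 0.432). SAT 1 peaks were then overlapped more often by VAT 1 (80.7%) than by VAT 2 (73.6%) or SAT 2 (69.4%). The same restriction left SAT 1 and VAT 1 as the closest pair, with a Jaccard index of 0.628. No 2 lists were copies, since at most 12 peaks had the same start and end in any pair.

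**Figure D1:**
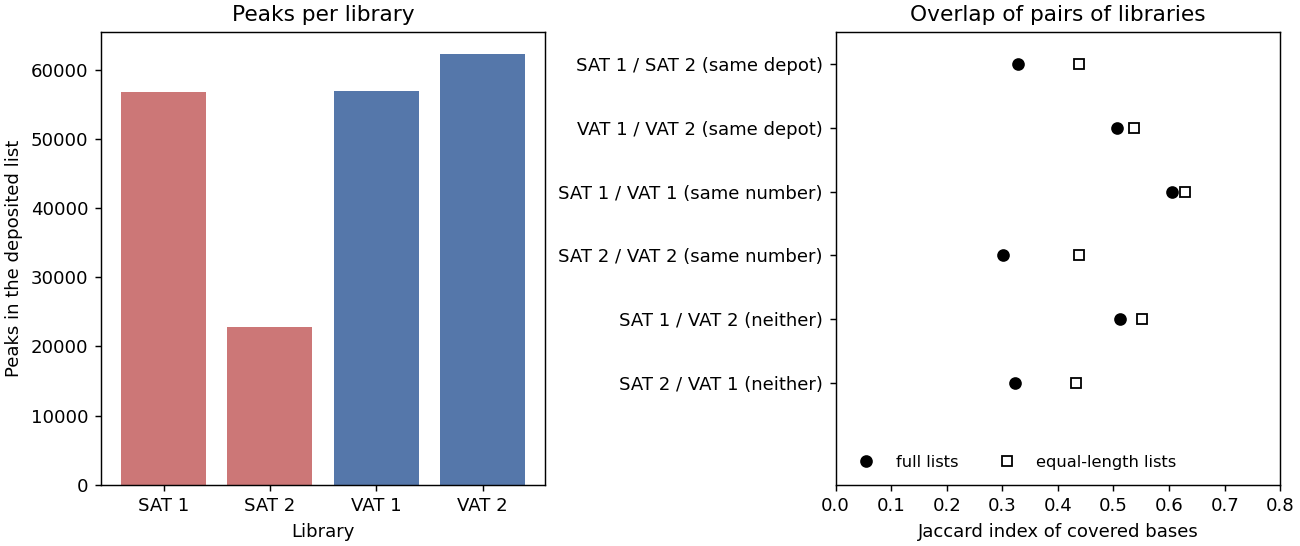
Left, number of peaks in each deposited list (bars; SAT subcutaneous in red, VAT visceral in blue; 1 library per bar). Right, Jaccard index of covered bases for the 6 pairs of libraries with the full lists (filled circles) and with the 22845 highest-scoring peaks of each list (open squares): SAT 1 and VAT 1 are the closest pair in both, at 0.605 and 0.628.

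Many regions were open in all libraries of both depots. The 4 lists merged into 83319 regions, and 19350 of them (23.2%) had a peak in all 4 libraries. These common regions were wide, with a median of 524 bp, and made up 10.9 Mb. Their peaks had a median score percentile of 80.4 in SAT 1, 80.3 in VAT 1 and 83.5 in VAT 2, but only 55.6 in the short list of SAT 2. A further 16206 regions had a peak in every library except SAT 2. The common regions with the highest scores were narrow. The leading pair lay on chromosome 12 at 3109840 to 3110142 and on chromosome 6 at 103599032 to 103599314, with scores of 2015 or more in all 4 libraries. No filter of repeats was applied here, and whether the submitters applied one is not given. Mapping artefacts at these positions can therefore not be told from open chromatin. These positions were named after their values were seen. Common regions were spread unevenly over chromosomes, and chromosome 7 held 1336 of them, which is 6.90% (95% Clopper-Pearson interval 6.55% to 7.27%) against 5.92% of all merged regions.

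The main comparison of the series was subcutaneous against visceral progenitors. The depots are those of the labels, which the lists do not verify, and each depot-restricted region rests on them. Restricted to subcutaneous progenitors, with a peak in SAT 1 and SAT 2 and none in either visceral list, were 92 regions. Another 3835 regions were restricted to visceral progenitors. This imbalance came with the difference in list length: with equal-length lists of 22845 peaks, 516 regions had peaks only in the subcutaneous and 624 only in the visceral lists. Nearly all of these were regions whose other peak ranked below the 22845 highest: 510 of the 516 (98.8%) and 603 of the 624 (96.6%) had a peak in the full list of a library of the other depot, which leaves 6 and 21 with none. Without SAT 2 the counts were 6633 and 4227, but a subcutaneous region then needs a peak in 1 library and a visceral region in 2, so that these counts do not say which depot has more. Regions restricted to a depot were weak and narrow. The subcutaneous ones had a median width of 158 bp and the visceral ones 205 bp. The weaker of their 2 peaks had a median score percentile of 14.6 in the subcutaneous and 17.3 in the visceral class, and in no such region did both peaks reach the percentile of 80. These traits were not particular to depot. Regions only in SAT 2 and VAT 1 had medians of 156 bp and 14.9, and those only in SAT 1 and VAT 2 of 200 bp and 17.9. Medians were higher for regions only in SAT 1 and VAT 1 (222 bp and 25.7) or only in SAT 2 and VAT 2 (240 bp and 21.3).

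Among regions restricted to visceral progenitors, the strongest lay on chromosome 11 at 108239511 to 108239671, with scores of 195 in VAT 1 and 198 in VAT 2. The next lay on chromosome 9 at 79791829 to 79792092, with scores of 184 and 173. It was followed by chromosome 18 at 56929885 to 56930106 (186 and 163), chromosome 14 at 77557478 to 77557763 (174 and 207) and chromosome 16 at 55519906 to 55520060 (172 and 186). The other 5 of the leading 10 lay on chromosomes 3, 4, 6, 1 and 7, and their weaker peaks stood between the percentiles of 67.6 and 70.1. When peaks within 500 bp were merged, 8 of the 10 kept their status. With the top 10000 peaks of each list, a setting added after seeing the data, 0 of the 10 visceral and 0 of the 10 leading subcutaneous regions remained, because at least 1 of their peaks ranked lower.

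Among regions restricted to subcutaneous progenitors, the strongest lay on chromosome 17 at 84239174 to 84239277, with scores of 130 in SAT 1 and 139 in SAT 2. A region on chromosome X at 94475822 to 94475944 had scores of 130 and 118. It was followed by chromosome 3 at 7204739 to 7204853 (140 and 97), chromosome 5 at 16886202 to 16886319 (138 and 97) and chromosome 12 at 105032938 to 105033077 (110 and 97). The remaining 5 of the leading 10 lay on chromosomes 8, X, 14, 16 and 9, with weaker peaks between the percentiles of 48.7 and 55.2. With equal-length lists 4 of the 10 remained, since the SAT 1 peak of the others stood below the score of 120 at which that list then ended.

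Along the genome, the largest number of visceral-restricted regions in a window of 1 Mb lay on chromosome 18 between 39 and 40 Mb, where 14 of 88 merged regions were restricted to visceral and 0 to subcutaneous progenitors. Windows of 1 Mb on chromosome 2 (165 to 166 Mb) and chromosome 5 (111 to 112 Mb) each held 10, and windows on chromosome 1 (135 to 136 Mb) and chromosome 11 (101 to 102 Mb) each held 9. By share, among windows with at least 20 merged regions, chromosome 1 from 168 to 169 Mb stood first, with 6 of 29 (20.7%), a ranking added after seeing the data. The window on chromosome 18 also held 9 regions found only in SAT 1 and VAT 2 and 6 found only in SAT 1 and VAT 1. Its net count depended on list length: with equal-length lists it was 1 region in favour of subcutaneous progenitors. Across the 1881 windows of 1 Mb with at least 10 merged regions, the counts of visceral-restricted regions were no more uneven than after shuffling the class among regions (dispersion index 0.976, shuffled range 0.894 to 1.14, p = 0.745 by a one-sided permutation test over regions with 1000 shuffles). The counts of subcutaneous-restricted regions were more uneven than nearly all shuffles (dispersion index 1.26, highest of the shuffles 1.30, p = 0.0030 by the same permutation test), and also with equal-length lists (1.14, highest of the shuffles 1.17, p = 0.0020).

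Subcutaneous-restricted regions had no autosomal window with a net count above 1. Their largest net counts were 3 regions on chromosome Y (1 to 2 Mb), 2 on chromosome Y (2 to 3 Mb) and 2 on chromosome X (122 to 123 Mb). These net counts depended on the setting. With equal-length lists they were 8, 3 and 6, and with the top 10000 peaks 6, 4 and 1. When peaks within 500 bp were merged they were 1, 0 and -1. Leaving out 1 library changes the rule unequally for the depots, so the net counts then do not say which depot has more. Without SAT 1 they were -6, -2 and -1, and without SAT 2 they were 10, 5 and 27. That on X was also -6 without VAT 1 and -13 without VAT 2. Chromosome X held 20 of the 92 regions, or 21.7% (95% Clopper-Pearson interval 13.8% to 31.6%), against 2.81% of all merged regions (two-sided Fisher's exact test across regions, which are not replicates, p = 1.04e-12). Of these, 16 lay between 120 and 123 Mb, where visceral-restricted regions also numbered 16, or 0.417% of the 3835. With equal-length lists, 27 of 516 subcutaneous-restricted and 0 of 624 visceral-restricted regions lay there. Chromosome Y held 6 of the 92, or 6.52% (2.43% to 13.7%), against 0.191% of all merged regions (same Fisher's exact test, p = 2.73e-08). Regions shared only by SAT 2 and VAT 1 were also frequent on chromosome X, with 11 of 80, or 13.8% (7.07% to 23.3%), but with equal-length lists this share was 2.93% (1.57% to 4.97%), against 2.79% of all regions. The subcutaneous-restricted shares then fell to 8.53% (6.26% to 11.3%) on X and 2.13% (1.07% to 3.78%) on Y, the latter against 0.343% of all regions. These intervals cover counting error only.

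**Figure D2:**
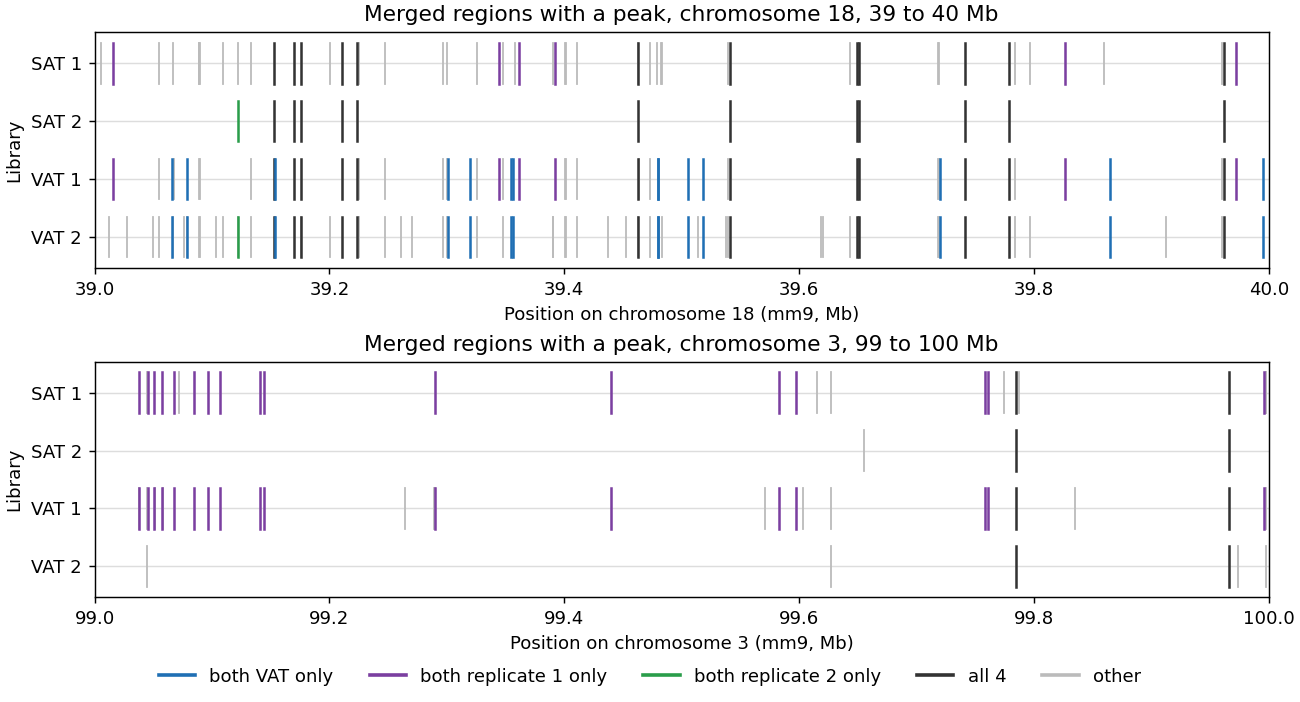
Position of merged regions (mm9, Mb) with a peak in each library (rows) in 2 windows of 1 Mb, coloured by the set of libraries that share the region. On chromosome 18, 14 regions were found in both VAT libraries only; on chromosome 3, 17 regions were found in both replicate 1 libraries (SAT 1 and VAT 1) only.

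The depot comparison was set beside the other 2 ways of dividing 4 libraries into 2 pairs. Dividing by replicate number gave more restricted regions than dividing by depot. SAT 1 and VAT 1 shared 7809 regions that were absent from both SAT 2 and VAT 2, and SAT 2 and VAT 2 shared 543 that were absent from the other pair. The crossed division gave 4110 regions for SAT 1 with VAT 2 and 80 for SAT 2 with VAT 1. In total, 8352 regions followed replicate number, 3927 followed depot and 4190 followed the crossed division. With equal-length lists these totals were 4040, 1140 and 1173, where absence means only that no peak ranked among the 22845 highest. Of these, 3118, 1113 and 1129 had a peak in the full list of a library of the other pair, which leaves 922 for replicate number, 27 for depot and 44 for the crossed division.

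**Figure D3:**
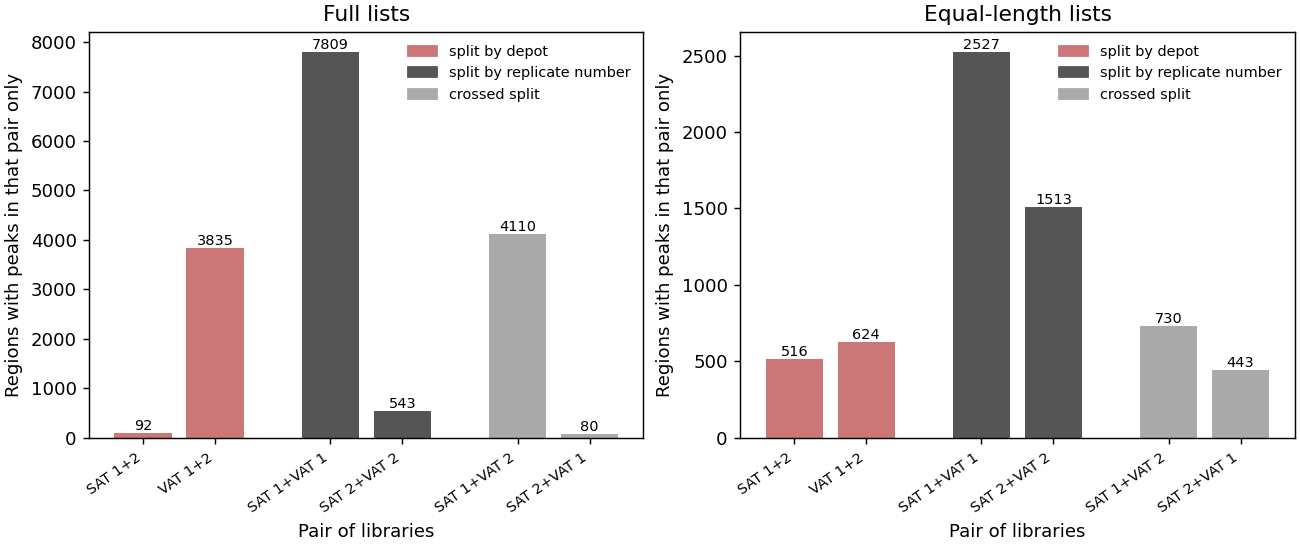
Number of merged regions with peaks in both libraries of a pair and in neither list of the other pair, for the 3 ways of dividing the 4 libraries, with the full lists (left) and equal-length lists of 22845 peaks (right). In both panels the bars for replicate number sum to more (8352 and 4040) than those for depot (3927 and 1140) or the crossed division (4190 and 1173).

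Because each division uses every library once, the product of its 2 counts is little affected by how long each list is. This measure was chosen after the counts were seen. The product for depot was 1.07 times that of the crossed division (log2 ratio 0.10 ± 0.23, SE over 21 chromosomes left out in turn), less than 1 SE from equality. The product for replicate number was 12.8 times that of the crossed division (log2 ratio 3.68 ± 0.25). With equal-length lists the ratios were 0.996 for depot (log2 ratio -0.0063 ± 0.18, with a 95% interval of 0.779 to 1.27 for the ratio itself) and 11.8 for replicate number (log2 ratio 3.56 ± 0.13). In the top 50% of each list the depot ratio was higher, with a log2 ratio of 0.90 ± 0.35, and on the autosomes of that top 50% it was 0.69 ± 0.39. With the full lists on autosomes only, the log2 ratio was -0.13 ± 0.23. These errors describe the spread over the genome in these 4 libraries, not the spread over animals.

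Regions that followed replicate number included strong peaks. Both peaks stood at or above the percentile of 80 in 88 of the regions found only in SAT 1 and VAT 1, in 1 region found only in SAT 2 and VAT 2, and in 0 regions of either depot class or of either crossed class. The strongest region of SAT 1 and VAT 1 lay on chromosome 18 at 42834310 to 42834654, with scores of 324 and 367. The strongest region of SAT 2 and VAT 2 lay on chromosome 2 at 104966472 to 104967013, with scores of 176 and 255. Among the 19350 common regions, scores ranked most alike in SAT 1 and VAT 1 (Spearman's rho 0.831 across regions, which are not independent replicates). The value was 0.755 for VAT 1 with VAT 2 and 0.669 for SAT 1 with SAT 2, and SAT 2 ranked most like VAT 2 (0.703). VAT 2, however, ranked more like VAT 1 and SAT 1 (0.750) than like SAT 2. The regions in this paragraph were named after their values were seen.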

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

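The counts of restricted regions were recomputed under the alternatives fixed before the data were examined, except the block for replicate number. The within-depot and between-depot overlap was recomputed with equal-length lists, the top 50%, 200 bp around each centre, each library left out, and the share of peaks overlapped. The differences in list values were recomputed with the block and with autosomes and X. The log2 ratios, and the settings with autosomes only, the top 10000 peaks, or without Y and X from 120 to 123 Mb, were added after seeing the data. The number of subcutaneous-restricted regions (92) moved to 516 with equal-length lists, 193 with 200 bp around each centre, 494 with 50% reciprocal overlap and 6926 when a peak in either library of the depot was enough. It was 304 with the top 10000 peaks, 478 with equal-length lists without Y and X from 120 to 123 Mb, and 57 in the top 50% on autosomes only. The number of visceral-restricted regions (3835) moved to 1947 in the top 50% of each list, 1895 in that part on autosomes only, 624 with equal-length lists (624 also without Y and X from 120 to 123 Mb), 349 with the top 10000 peaks and 27320 with a peak in either library. Leaving out 1 library at a time gave 298 to 6633 subcutaneous-restricted and 4227 to 20417 visceral-restricted regions. The highest subcutaneous count came without SAT 2, and the highest visceral count without VAT 1; without SAT 1 the visceral count was 20145, and without VAT 2 it was 11403. The counts rise by construction, since 1 library then stands for a depot. The difference in Jaccard index lay between -0.135 and 0.195 when 1 library was left out, and it was positive only without SAT 1. The log2 ratio of depot over the crossed division differed from 0, by its 95% interval, only in the top 50% of each list (0.90), and the cause was not tested. That of replicate number over the crossed division stayed between 2.42 and 3.90 in all settings run. The replicate number as a block cannot move the visceral minus subcutaneous differences in this balanced design (19759 peaks, 6.35 Mb and 10 bp), and it gave p = 0.5 by an exact sign-flip permutation test over pairs, the smallest p that 2 pairs allow; the difference in peaks was 84 between the replicate 1 and 39434 between the replicate 2 libraries. Among the named windows, the net count changed sign on chromosome 18 (39 to 40 Mb) to 1 with equal-length lists, also without Y and X from 120 to 123 Mb. With the top 10000 peaks it changed sign to 1 on chromosome 2 (165 Mb), 1 on chromosome 1 (135 Mb) and 2 on chromosome 11 (101 Mb). Merging within 500 bp turned chromosome X (122 Mb) to -1. Leaving out 1 library at a time gave net counts from -13 to 27 on chromosome X (122 Mb), -6 to 10 on chromosome Y (1 Mb), -2 to 5 on chromosome Y (2 Mb), -1 to 1 on chromosome 1 (49 Mb) and -2 to 4 on chromosome 1 (79 Mb). The cause of these changes was not tested. Depth is not given in the lists, so a region absent from SAT 2 cannot be told from one below its detection limit.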

Other observations

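The tests in this part were all chosen after the results were seen. Regions found only in SAT 1 and VAT 1 formed local groups. On chromosome 3 between 99 and 100 Mb, 17 of 38 merged regions were of this kind, and 0 were restricted to either depot. Of these, 10 lay within 106 kb, from 99038030 to 99144254, where SAT 2 had 0 peaks and VAT 2 had 1, against 12 regions with a SAT 1 peak and 13 with a VAT 1 peak. Other windows with a high share were chromosome 14 from 10 to 11 Mb (10 of 21 regions) and chromosome 3 from 131 to 132 Mb (16 of 41), and the largest number was on chromosome 1 from 92 to 93 Mb (23 of 116).

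Regions found only in SAT 2 and VAT 2 were fewer, and several of the strongest lay near each other. On chromosome 2, a region at 104966472 to 104967013 (scores 176 and 255) and another at 104986858 to 104987364 (128 and 211) both ranked among the leading 10. A second pair on the same chromosome lay at 74803542 to 74803838 (139 and 174) and at 74996559 to 74996972 (139 and 182). The strongest others lay on chromosome 13 at 4782604 to 4782917 (150 and 262), chromosome 8 at 113494126 to 113494447 (153 and 196) and chromosome 1 at 158938200 to 158938780 (141 and 246).

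The pattern that most calls for a second look is that regions shared by only 2 libraries followed replicate number more than depot. By Jaccard index SAT 1 and VAT 1 were the closest pair (0.605). SAT 2 and VAT 2 were the least close with the full lists (0.301), where every pair with the short SAT 2 list was low. With equal-length lists SAT 2 had an index of 0.439 with VAT 2, 0.437 with SAT 1 and 0.432 with VAT 1. The short list of SAT 2 does not account for the pattern, since the log2 ratio of replicate number over the crossed division was 3.56 ± 0.13 with lists of equal length. Regions found only in SAT 1 and VAT 1 were clumped in 1 Mb windows beyond all shuffles (dispersion index 1.98, highest of 1000 shuffles 1.10). Those found only in SAT 2 and VAT 2 had an index of 1.10 (highest of the shuffles 1.12, one-sided permutation p = 0.022, and p = 0.157 with equal-length lists). The shuffles moved the class among regions without regard to peak score. They therefore cannot decide on a difference in signal over background that is even across the genome, which stays open for both classes. A candidate explanation is an exchange of labels, either between SAT 2 and VAT 1 or between SAT 1 and VAT 2. Both exchanges give the same pairs, so the lists alone cannot tell which is more likely. Genes were not looked up at the group on chromosome 3 (99038030 to 99144254), found mainly in SAT 1 and VAT 1. Nor were they at the strongest region of SAT 2 and VAT 2, on chromosome 2 (104966472 to 104967013). After either exchange, regions restricted to a depot by label would not be so by tissue. An exchange needs no excess for the depot division. The log2 ratio of depot over the crossed division was -0.0063 ± 0.18 with equal-length lists. In the top 50% of each list it was 0.90 ± 0.35, an excess that the exchange alone does not predict. Shared animals, a shared day or a shared preparation for each replicate number could give the same log2 ratio of 3.68 in the full lists. If the labels are correct, a depot difference beside a shared origin would raise the depot ratio, as in the simulated lists (6.17 ± 0.15). In the full lists the depot log2 ratio was 0.10 ± 0.23, so a shared origin with correct labels needs a weak depot difference there. How weak cannot be said, since smaller effects were not simulated. What keeps an exchange and a shared origin open here is that the labels give no animal, day or batch. The regions were also not compared with marker genes of the depots, which an annotation of build mm9 would allow.

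The crowding of subcutaneous-restricted regions on chromosome X from 120 to 123 Mb may come in part from SAT 2, which had 0.998% of its peaks there, against 0.639% in SAT 1, 0.562% in VAT 1 and 0.464% in VAT 2. Of the other classes with SAT 2, that shared only with VAT 1 was enriched there (12.5% of its regions, 95% interval 6.16% to 21.8%, against 0.611% of all merged regions), but that shared only with VAT 2 was not set apart (1.10%, 0.407% to 2.39%), and on chromosome Y the class of SAT 2 and VAT 1 held 1 of 80 regions, an interval that includes the share of all regions. With equal-length lists 5.23% of subcutaneous-restricted regions (3.48% to 7.52%) lay in that part of X, against 1.35% (0.499% to 2.92%) of regions shared only by SAT 2 and VAT 1 and 0.264% (0.0721% to 0.676%) of those shared only by SAT 2 and VAT 2. Of the 624 visceral-restricted regions, 0 lay there. SAT 2 then had 228 peaks in that part of X, SAT 1 had 101, VAT 1 had 65 and VAT 2 had 62. Both a larger share in SAT 2 and a difference between the depots stay open, since the classes with SAT 2 differ and there are 2 libraries per depot. The same part of X held up to 204 merged regions per 1 Mb, against a median of 29 over all windows with a region. No filter of repeats was applied here, and none by the submitters is known. Mapping artefacts in this part of X and on chromosome Y can therefore also not be told from open chromatin, and this was not tested.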
